A study of Mus musculus with 3 samples.

How the data were processed

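The 3 libraries hold polyadenylated RNA, 1 for each of 3 replicates of microvascular fragments isolated from the brains of adult C57BL/6J mice. Per the labels' protocols, brain tissue was broken up mechanically and with enzymes, vascular fragments were collected, and stranded messenger RNA libraries with unique dual indexes were made from 400 ng of total RNA and sequenced as paired reads of 150 bp. All 3 libraries belong to 1 group, so no contrast between conditions exists and every comparison below is between gene lists within these libraries or between the 3 mice. Replicate numbers came from the sample titles. The series' design text speaks of 3 mice; the labels call the mice adult and give no sex, exact age, date or batch. The replicates were taken as separate mice on that text.

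The deposited table holds whole-number counts per gene. Per the submitters' processing notes, the authors' tools were featureCounts and Subread 1.4.6-p5 and the build was GRCm39. The aligner, the annotation release, the strand setting, the treatment of reads that map to several places and whether read pairs or single reads were counted are not given in the sources used here. Counts were not normalized. The table has 56941 genes named by symbol, of which 310 carry only an Ensembl identifier; 26428 genes have no count in any library. No row stands for unassigned reads, and every column was mapped to a sample. Depth was 128428355, 136672205 and 150449539 counts in replicates 1, 2 and 3. A count of 0 therefore allows up to 0.0234, 0.0220 and 0.0199 CPM (3 counts of the library total), which covers counting error only, since the labels name no molecular identifiers. Tests of the counts of each pair of libraries against sampling noise over the 13211 detected genes gave a mean chi-square of 198 to 264 per gene on 1 degree of freedom, so no library is a copy of another.

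From the counts, CPM (counts scaled to a common library total) were computed with effective library sizes from edgeR 4.0.16 (TMM normalization, R 4.3.3), and lists were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. TMM factors were 1.01, 1.02 and 0.965. A gene was called detected at 1 CPM or more in every library. Levels are CPM with the SD over 3 libraries; for lists, the median over all measured members of each gene's mean log2(CPM + 1), with the SD of the medians of the 3 libraries. The plan fixed beforehand named the mean of the library medians instead; the level used lies within the range of the library medians except for the venous list, and the differences lie within the range of the single mice except for capillary against venous, where the single values are printed. The pseudocount of 1 understates differences among genes near 0. CPM is not scaled by gene length, so levels of different genes also differ by length; an alternative divided CPM by the exonic length of each gene in GENCODE M21 (build GRCm38, matched by symbol, 49083 genes holding 98.3% of the counts). That annotation is of another build than the table, so it served only for lengths, exon overlap and sequence identity, and no coordinates are given.

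In all, 30 gene lists were fixed before the data were examined: 12 of cell type markers with no gene in common, and 18 of vascular, response and control genes. They hold 361 genes, of which 360 are in the table (the erythroid marker Ahsp was not found by symbol). The endothelial list was compared with each of the other 11 cell type lists, and the arterial, capillary and venous lists with each other, by two-sided permutation tests across genes on the difference of medians (100000 resamples, smallest possible p 1e-05; an exact test for the 9 erythroid genes), adjusted by Benjamini-Hochberg over the 11 and the 3 tests. Genes are not independent replicates, so these p-values describe the lists and not the mice. A sign-flip test over 3 mice cannot go below 0.25; the SD over mice is given in its place. Each list's median was also placed among 10000 random lists of the same size drawn from the detected genes.

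Variability between mice was tested gene by gene in edgeR. An intercept-only quasi-likelihood model was fitted to the 18087 genes kept by filterByExpr, and each gene's quasi-dispersion was compared with the trended prior by an upper-tail F test with Benjamini-Hochberg adjustment at 0.05. That filter asks for counts in all 3 libraries and so leaves out genes present in only 1. On simulated counts with 200 genes shifted in 1 library, the test recovered 3.5% of 2-fold, 81.5% of 4-fold and 94% of 8-fold shifts with at most 1 false call, over 17750 to 17767 genes. The simulated genes all lay on the dispersion trend, without scatter of their own around it, and genes with low counts were not shifted. Recovery among the real genes can therefore be lower, and a gene that was not called may still differ several-fold. For lists, the mean deviation of the detected members from their own means was taken per library, and its SD over libraries was placed among 10000 random lists matched on expression. The permutation test of lists was tested on simulated levels of 28 genes and called 6.5% of runs with no difference, 22.5% with a difference of 1 and 95% with a difference of 3 on the log2 scale, so a difference near 1 is often missed.

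Named genes are members of the 30 lists, the 20 genes with the highest mean CPM outside the mitochondrial genome, and the 10 genes with the smallest adjusted p for variability. List examples are the highest and lowest members or those a list is named for. Genes named outside this rule are marked as chosen after their values were seen. Alternatives were DESeq2 1.42.0 size factors, library totals without further scaling, totals without mitochondrial genes, pseudocounts of 0.25, list means, leaving out low members, length scaling, other detection limits and filters, other dispersion tests, and leaving out each replicate. Sequence identity of mitochondrial messengers to nuclear transcripts was searched with BLAST 2.17.0.

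The authors' strand setting matters for genes that share exonic sequence with a neighbour on the other strand, but not for overlap on the same strand. Among list genes, 13 have more than 30% of their exonic length under exons of another gene on either strand in GENCODE M21. Among them are Ctnnd1, Foxq1, Igf2, Jam3, Jund, Kcnj13, Lsr, Nefl, Notum, Pln, Rarres2 and Tagln. For Ctnnd1 and Igf2 the overlap is mainly on the same strand, at 61.2% and 62.8% of exonic length. The levels of all 13 genes are uncertain. The same holds for the near-identical alpha globin genes Hba-a1 and Hba-a2, the beta globin genes Hbb-bs and Hbb-bt, the heat shock genes Hspa1a and Hspa1b, and mitochondrial messengers with nuclear copies.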

Results

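Bulk RNA sequencing was used to describe the transcripts of brain microvascular fragments, short pieces of small vessel freed from adult mouse brain that keep the endothelium together with the cells attached to it. The 3 libraries came from wild-type C57BL/6J mice and form a single group (n = 3), with no untreated brain, sorted cell or other control beside them. Depth ranged from 128428355 to 150449539 counts per library. At 1 CPM or more in every library, 13211 genes were detected, of which 1964 reached 100 CPM and 85 reached 1000 CPM in all 3. Of the detected genes, 12826 could be matched by symbol to GENCODE M21, and 12252 of these are annotated there as protein coding. Across the 30513 genes with any count, log2(CPM + 1) correlated between pairs of libraries with Pearson's r = 0.996 to 0.997 and Spearman's rho = 0.962, where genes are not independent replicates. The common biological coefficient of variation in edgeR was 0.210.

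The most abundant transcripts included several of the endothelial, barrier and basement membrane markers. Bsg, which encodes basigin, a partner protein of monocarboxylate transporters, was the highest nuclear gene at 9702 ± 809.7 CPM (SD, n = 3). The proteoglycan gene Spock2 followed at 6334 ± 1279 CPM, and Slc2a1, the glucose transporter of the blood-brain barrier, stood at 5776 ± 1409 CPM. The VEGF receptor Flt1 had 3852 ± 412 CPM, the matrix gene Sparc 3518 ± 108 CPM, its relative Sparcl1 3540.3 ± 195 CPM and the tight junction gene Cldn5 3458 ± 555 CPM. Pltp, a phospholipid transfer protein, had 3341 ± 306 CPM, the hypoxia-inducible factor Epas1 3157 ± 182 CPM, Fn1 (fibronectin) 2850.3 ± 619 CPM and Itm2a 2464 ± 227 CPM. Ly6c1, an endothelial surface marker, stood at 2481 ± 546 CPM. Ttr, the transthyretin gene that choroid plexus epithelium expresses at very high level, was among these genes too, at 6282 ± 1500.2 CPM. The rest of the 20 highest nuclear genes were Eef1a1, Cst3, Actb, App, Sptbn1, Serinc3 and the ribosomal sequence Rn18s-rs5, which had 3276, 1724 and 3698 CPM in replicates 1, 2 and 3.

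Marker genes of endothelial cells stood far above those of neurons and of the oligodendrocyte lineage. All 16 endothelial markers were detected, and their median was 10.07 ± 0.15 on the log2(CPM + 1) scale (SD, n = 3), above all 10000 random lists of detected genes. Examples besides Flt1 and Cldn5 were Ly6a at 2192 ± 381 CPM, Ptprb at 2016 ± 22.2 CPM, Eng at 1663 ± 238 CPM, Pecam1 at 1437 ± 195 CPM, Cdh5 at 1068 ± 60.9 CPM and Kdr at 899 ± 137 CPM, down to Egfl7 at 273 ± 50.4 CPM and Erg at 261 ± 17.9 CPM. Neuronal markers had a median of 2.43, with 10 of 12 detected. Stmn2 was the highest at 79.4 ± 8.89 CPM, while Snap25 had 8.65 ± 5.90 CPM, Syt1 6.69 ± 0.370 CPM and Rbfox3 1.68 ± 0.208 CPM. Oligodendrocyte markers had a median of 2.26, with 7 of 12 detected. Mbp, a main myelin gene, was low (67.1 ± 4.28 CPM) beside Mal at 715 ± 203 CPM. Precursor markers had the lowest median of the cell type lists, 1.10, with Pdgfra at 6.08 ± 0.676 CPM and 5 of 10 detected. The list of perivascular macrophages and leukocytes had a median of 1.44 with 6 of 14 detected, led by Mrc1 at 10.7 ± 2.87 CPM and Cd163 at 5.16 ± 0.607 CPM.

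**Figure D1:**
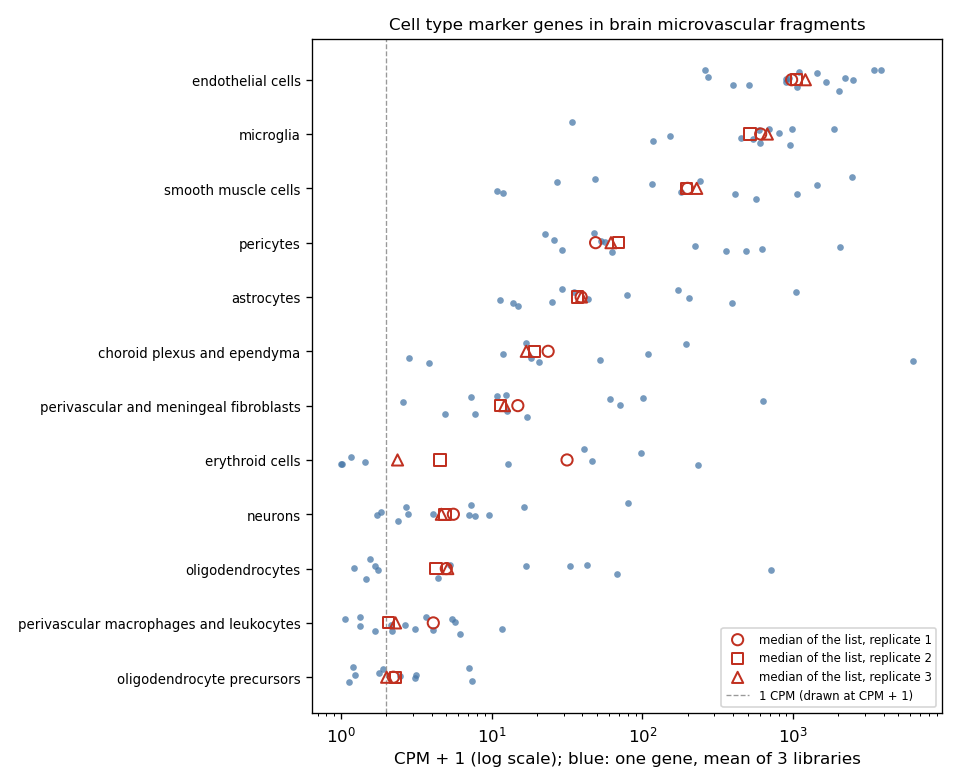
Levels of the cell type marker genes, 1 row per list. The x axis is CPM + 1 on a log scale, each blue point is the mean of 1 gene over the 3 libraries, and red open symbols are the median of the list in each replicate. Endothelial and microglial medians lie at the top, and the erythroid medians are the most spread between replicates.

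Marker genes of the other cells of the vessel wall and its surroundings were detected at graded levels. These levels depend on the genes chosen and on their length, so they do not give the share of each cell type. Smooth muscle genes had a median of 7.70 ± 0.13, with the contractile genes Acta2 at 2461 ± 303 CPM, Myh11 at 1438 ± 72.9 CPM and Myl9 at 1061 ± 54.4 CPM. Tagln, another contractile gene, had only 10.9 ± 1.42 CPM; 67.9% of its exonic length lies under the exons of Gm48529 on the other strand, so its count is uncertain. Pericyte genes had a median of 5.88 ± 0.26, from Rgs5 at 2044 ± 184 CPM, Vtn at 625 ± 101 CPM, Notch3 at 487 ± 22.4 CPM and Pdgfrb at 360.1 ± 31.0 CPM down to Kcnj8 at 28.4 ± 6.49 CPM and Cox4i2 at 21.5 ± 3.11 CPM. All 12 members of both lists were detected. All 12 microglial genes were detected as well, with a median of 9.21 ± 0.19. The microglial growth factor receptor Csf1r reached 1860.0 ± 235 CPM and the chemokine receptor Cx3cr1 987 ± 130.2 CPM, while Tmem119 had 543 ± 109 CPM, P2ry12 447 ± 141 CPM and Aif1 33.3 ± 1.99 CPM. Astrocyte genes had a median of 5.27 ± 0.05, with the glutamate transporter Slc1a2 at 1047 ± 366 CPM, Gfap at 33.9 ± 4.93 CPM and the endfoot water channel Aqp4 at 24.0 ± 7.49 CPM. Fibroblast genes had a median of 3.63 ± 0.20, led by Mgp at 626 ± 77.5 CPM, with Col1a2 at 100.3 ± 6.65 CPM, Dcn at 11.5 ± 3.54 CPM and Lum at 1.59 ± 0.610 CPM. Choroid plexus and ependymal genes had a median of 4.26 ± 0.24; behind Ttr came Kl at 194 ± 66.9 CPM, Clic6 at 108 ± 32.1 CPM and Folr1 at 51.6 ± 11.5 CPM.

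The endothelial median exceeded that of 10 of the 11 other cell type lists in the permutation test across genes (two-sided, adjusted p from 0.000176 to 0.00165), and it was the higher one in 3 of 3 mice against each of the 11. The difference was 2.37 ± 0.07 (SD over 3 mice) against smooth muscle cells, 4.19 ± 0.22 against pericytes, 4.80 ± 0.15 against astrocytes, 5.81 ± 0.39 against choroid plexus and ependyma and 6.44 ± 0.32 against fibroblasts. It was 7.27 ± 2.08 against erythroid cells, 7.65 ± 0.28 against neurons, 7.82 ± 0.18 against oligodendrocytes, 8.63 ± 0.65 against macrophages and leukocytes and 8.97 ± 0.25 against oligodendrocyte precursors. The difference from microglia, 0.86 ± 0.17, did not pass the permutation test (adjusted p = 0.0606). It passed without replicate 1 (difference 0.93, adjusted p = 0.0466) and with list means (1.32, adjusted p = 0.0170), and it turned to -0.32 (adjusted p = 0.528) when genes were scaled by length, each by the permutation test. Among the other differences, length scaling gave 2.51 for pericytes and 4.39 for choroid plexus and ependyma, and leaving out members under 1 CPM gave 5.08 for oligodendrocytes and 5.43 for erythroid cells. Leaving out genes with overlapped exons, chosen after seeing the data, gave 1.78 for smooth muscle cells (permutation test, adjusted p = 0.0204), and all of these stayed past the threshold.

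Genes of the blood-brain barrier were detected almost without exception and most were abundant. Of the 19 junction genes, 18 were detected, with a list median of 8.60 ± 0.11. The highest besides Cldn5 were Ctnnb1 (1573 ± 71.8 CPM) and Pecam1, and the list also held the scaffold gene Tjp1 at 914 ± 49.2 CPM, Ocln (occludin) at 469 ± 53.0 CPM and the tricellular junction gene Lsr at 196 ± 35.6 CPM. Cldn12 had 19.2 ± 2.85 CPM and Cldn3 only 1.78 ± 0.689 CPM. All 15 solute carriers were detected, with a median of 9.34 ± 0.12. Behind Slc2a1 stood the amino acid transporter Slc7a5 at 2065 ± 503 CPM, its partner Slc3a2 at 902 ± 182 CPM, the organic anion carriers Slco1a4 at 1999.8 ± 234 CPM and Slco1c1 at 1716 ± 176 CPM, and the taurine transporter Slc6a6 at 1809 ± 86.4 CPM. Among the 9 efflux pumps, all detected with a median of 5.65 ± 0.12, Abcb1a (P-glycoprotein) had 1486 ± 161 CPM and Abcg2 592 ± 69.0 CPM, against the paralog Abcb1b at 5.28 ± 0.673 CPM. All 14 vesicle transport genes were detected, with a median of 8.14 ± 0.13. They included Cav1 at 603 ± 85.5 CPM, the lipid transporter Mfsd2a at 375 ± 116 CPM, the transferrin receptor Tfrc at 162 ± 7.65 CPM and Plvap, a gene of fenestrated endothelium, at 104 ± 4.82 CPM. All 17 genes of canonical Wnt signalling were detected, with a median of 7.87 ± 0.16, from Apcdd1 at 926 ± 164 CPM, Adgra2 at 384 ± 43.1 CPM and the Norrin receptor Fzd4 at 372 ± 16.9 CPM to Lef1 at 191 ± 9.52 CPM, Axin2 at 90.4 ± 14.0 CPM and Notum at 27.3 ± 5.78 CPM. The 16 basement membrane genes were all detected, with a median of 8.32 ± 0.10. Col4a1 had 1488 ± 272 CPM, Col4a2 1146 ± 183 CPM, Lamb2 867 ± 81.2 CPM and Lama1 10.3 ± 3.01 CPM. Over all 30 lists, 15 medians lay at or above the 95th percentile of random lists. The junction, solute carrier, vesicle, Wnt and basement membrane medians lay above all of the 10000 random lists, whereas the efflux pump median lay at percentile 85.6, or 99.8 with list means.

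**Figure D2:**
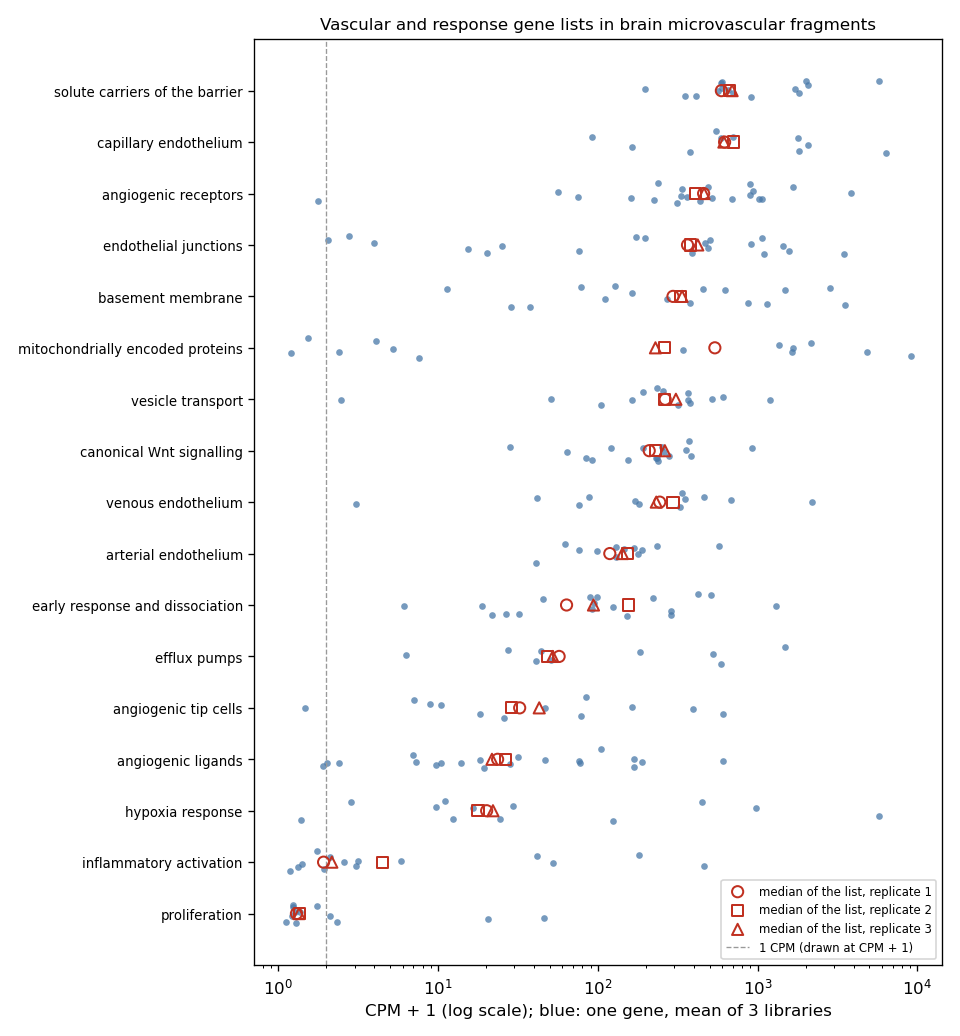
Levels of the vascular, response and control gene lists, 1 row per list and drawn as CPM + 1 on a log scale. Blue points are means of single genes over the 3 libraries and red open symbols are list medians per replicate. Solute carriers and capillary genes have the highest medians and proliferation genes the lowest, and the early response medians differ between replicates.

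Genes of all 3 segments of the vascular tree were detected, and capillary genes were the most abundant. The capillary list had a median of 9.33 ± 0.11, with Spock2, Slc7a5, Cxcl12 (1778 ± 442 CPM) and Car4 (544 ± 87.5 CPM). The venous list had 7.84, with library medians of 7.93, 8.21 and 7.86, and held Vwf (2194 ± 378 CPM), Vcam1 (463 ± 224 CPM) and Nr2f2 (86.9 ± 17.8 CPM). The arterial list had 7.09 ± 0.19, with Sema3g (570.0 ± 86.7 CPM), Gkn3 (176 ± 35.3 CPM), the Notch ligand Dll4 (167 ± 35.9 CPM) and Bmx (61.4 ± 4.71 CPM). The capillary median was 2.24 ± 0.14 above the arterial one (SD over 3 mice, higher in 3 of 3 mice; permutation test across genes, two-sided, adjusted p = 0.00675). The 1.48 between capillary and venous lists (1.35, 1.25 and 1.41 in the single mice) and the -0.75 ± 0.17 between arterial and venous lists did not pass (adjusted p = 0.108 for both, permutation test). The capillary and venous lists did differ with length scaling (2.02, adjusted p = 0.0195) and with list means (2.17, adjusted p = 0.0388), by the same permutation test.

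Genes of angiogenic receptors were abundant, those of angiogenic ligands had a median within the range of random lists (percentile 33.7), and those of cell division were low. Of 21 receptors, 20 were detected, with a median of 8.76 ± 0.10. Besides Flt1, Kdr and Eng these included S1pr1 at 1071 ± 130.0 CPM, Acvrl1 at 1022 ± 149 CPM, Tek at 934 ± 39.99 CPM, Notch4 at 332 ± 122 CPM and Notch1 at 314 ± 61.7 CPM; Met was under the limit at 0.769 ± 0.0942 CPM. Of 20 ligands, 18 were detected, with a median of 4.54 ± 0.14. Pdgfb led at 602 ± 137 CPM, Tgfb1 had 169 ± 26.0 CPM and Angpt2 45.5 ± 9.52 CPM, whereas Vegfa had 8.66 ± 1.72 CPM, Fgf2 6.02 ± 0.755 CPM and Hgf 0.895 ± 0.109 CPM. Of the 12 tip cell genes, 11 were detected, with a median of 5.10 ± 0.30; Mcam had 390.1 ± 26.1 CPM, Apln 17.3 ± 3.42 CPM and Esm1 9.39 ± 3.44 CPM. Only 3 of 12 proliferation genes were detected, with a median of 0.40 ± 0.04. These were Pcna at 45.1 ± 3.40 CPM, Mcm2 at 19.4 ± 1.75 CPM and Cdk1 at 1.32 ± 0.0592 CPM, and Mki67 had 0.750 ± 0.103 CPM. Of the 12 genes of the hypoxia response, 11 were detected, with a median of 4.33 ± 0.16 and a range from Slc2a1 and Ndrg1 (976 ± 242 CPM) to Car9 (0.379 ± 0.181 CPM). The 14 genes of inflammatory activation had a median of 1.36 ± 0.66 with 6 detected. Il1b had 1.09 ± 0.468 CPM, Il6 0.414 ± 0.156 CPM and Tnf 0.178 ± 0.0192 CPM, but the adhesion molecule genes Vcam1 and Icam1 (179 ± 109 CPM) were well above these.

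Transcripts of globin and pituitary hormone genes differed widely between the mice. By edgeR's quasi-likelihood dispersion test, 15 of 18087 genes varied more than the trend at an adjusted p under 0.05. Hormone genes of the anterior pituitary were high in replicate 2 alone. Gh (growth hormone) had 0.108, 1233 and 0.262 CPM in replicates 1, 2 and 3 (adjusted p = 0.00171), Prl (prolactin) 26, 6677 and 69 counts (adjusted p = 0.00504), and Cga, the shared subunit of the glycoprotein hormones, 120, 6295 and 165 counts (adjusted p = 0.00975). Dlk1 and the secretory granule gene Scg2 were highest in replicate 2 too, with 0.807, 21.9 and 0.496 CPM and 3.78, 55.5 and 5.15 CPM (adjusted p = 0.0133 for both). The globin genes were highest in replicate 1, with Hbb-bs at 599, 69.8 and 32.6 CPM (adjusted p = 0.0156), Hba-a1 at 245, 32.8 and 14.8 CPM and Hba-a2 at 112, 15.2 and 7.52 CPM (adjusted p = 0.0133 for both), likewise Hbb-bt at 102, 12.6 and 6.15 CPM and the heme synthesis gene Alas2 at 30.6, 3.54 and 1.37 CPM. The remaining calls, named after their values were seen, were Pomc, Elapor1, Ccn1, Chga and Chgb, all highest in replicate 2. Single libraries decide this count. Without replicate 1 the test called 7 genes, all among the 15; without replicate 2 it called 80, with 6 of the 15; without replicate 3 it called 33, with all 15. With a robust prior edgeR called 0 genes, with 785 at an unadjusted p under 0.05, and DESeq2 marked 111 dispersion outliers, the 15 among them.

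**Figure D3:**
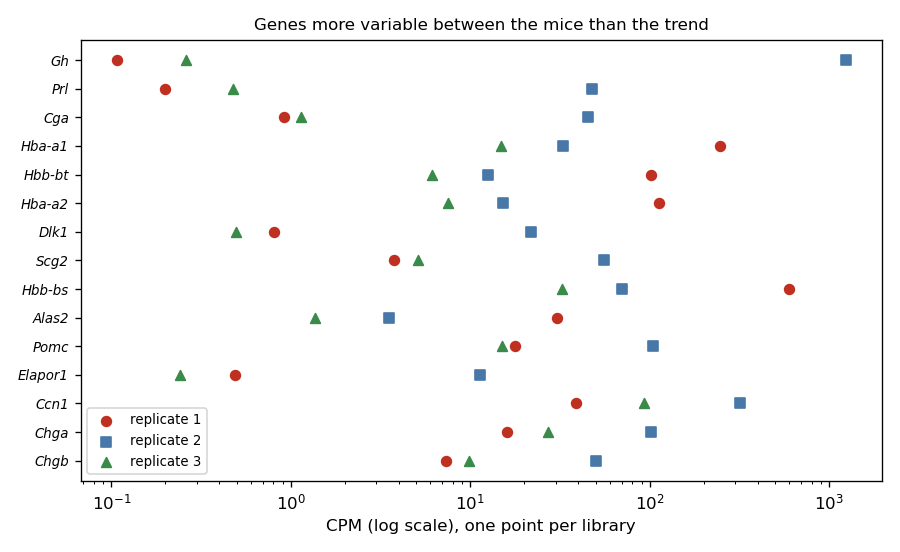
CPM on a log scale of the 15 genes that varied more between the mice than the trend, 1 point per library. The globin genes and Alas2 lie highest in replicate 1, and all other genes drawn, among them Gh, Prl, Cga and Ccn1, lie highest in replicate 2.

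Whole lists also shifted between the mice. For 16 of the 29 lists with at least 3 detected members, the spread of the list mean over libraries lay above the 95th percentile of random lists matched on expression. The random lists were drawn gene by gene, so genes of a list that vary together exceed them more easily, and some lists share genes. The count therefore describes these libraries and is not a test against chance. Early response genes had mean log2 deviations of -0.63, 0.61 and 0.02 in replicates 1, 2 and 3. Fos had 13.7, 86.6 and 32.6 CPM, Egr1 32.2, 184 and 57.8 CPM, Dusp1 244, 706 and 580 CPM and Nr4a1 42.0, 229 and 98.3 CPM, and none of these passed the single-gene test (edgeR adjusted p of 0.0529 or more); the list median was 6.56 ± 0.65. Inflammatory activation genes deviated by -0.54, 0.69 and -0.15, with Icam1 at 83.2, 298 and 156 CPM and Vcam1 at 271, 709 and 408 CPM. That deviation rests on the 6 of 14 members that were detected. Among these, Vcam1, Icam1, Selp and Lcn2 are also in the venous list, so the shifts of the inflammatory and venous lists are not separate. Erythroid genes deviated by 2.26, -0.63 and -1.63, with a list median of 2.80 ± 1.94, and the macrophage and leukocyte list by 0.31, -0.21 and -0.10. Mitochondrially encoded messengers deviated by 0.65, -0.33 and -0.31, and mitochondrial genes held 3.29%, 1.75% and 1.65% of the counts; mt-Co1 had 9078 ± 3479 CPM and the list median was 8.31 ± 0.67. Among the cell type lists, endothelial genes deviated by -0.17, 0.01 and 0.16, pericyte genes by -0.16, 0.14 and 0.02, microglial genes by 0.14, -0.20 and 0.06, astrocyte genes by 0.09, 0.16 and -0.25, and choroid plexus genes by 0.21, -0.01 and -0.20. Neuronal genes deviated by 0.18, -0.08 and -0.11, smooth muscle genes by 0.07, -0.17 and 0.09, and fibroblast genes by 0.15, -0.09 and -0.06. Of the vascular lists, venous genes deviated by -0.21, 0.19 and 0.02, capillary genes by -0.24, 0.11 and 0.13 and Wnt genes by -0.13, 0.03 and 0.10, while the junction, solute carrier, efflux pump, arterial and angiogenic receptor lists lay below the 95th percentile. Without replicate 1 the number of lists above it was 9: the endothelial, capillary, venous, Wnt, pericyte, fibroblast, neuronal, macrophage and leukocyte, and mitochondrial lists dropped out, and the tip cell and angiogenic ligand lists came in. Without replicate 2 the microglial (percentile 29.0), smooth muscle (14.6) and pericyte (94.5) lists dropped out. Without replicate 3 the astrocyte list dropped out (70.5), and the oligodendrocyte (95.7) and solute carrier (95.3) lists came in.

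Sex-linked genes separated the libraries, although the labels give no sex. Xist, the RNA of the inactive X chromosome, had 48.0, 0.00715 and 27.9 CPM in replicates 1, 2 and 3, the second of these resting on 1 count. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 45.6, 17.5, 16.7 and 12.8 CPM in replicate 2. In replicates 1 and 3 they had no count, except 1 count of Ddx3y in replicate 1. These 5 genes were too low in at least 1 library to enter the variability test. By these genes, replicate 2 had the pattern of a male and replicates 1 and 3 that of females. Any difference of replicate 2 from both other libraries therefore cannot be told apart from a difference of sex.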

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

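Leaving out genes whose exons overlap another gene was chosen after seeing the data, and the other alternatives were fixed before the data were examined. The endothelial median stayed above that of the 10 lists it exceeded, past the threshold, under all of the scaling, pseudocount, list mean, low-member, length, overlap and leave-one-out alternatives, and the capillary median likewise stayed above the arterial one. The difference between endothelial and microglial lists reversed with length scaling (-0.32) and passed the threshold with list means (1.32) and without replicate 1, with a range of 0.77 to 0.93 over the libraries left out; length scaling by construction lowers the level of long genes, and for the other changes the cause was not tested. The difference between capillary and venous lists passed with length scaling (2.02) and list means (2.17); the cause was not tested. The mean Pearson's r moved from 0.997 to 0.996 with a pseudocount of 0.25 and to 0.994 over filterByExpr genes only, and was 0.996 to 0.997 over the pairs left by leave-one-out. The biological coefficient of variation was 0.180 over filterByExpr genes, 0.216 with library totals alone and 0.198 to 0.204 with a library left out. The count of variable genes depended most on the test. It was 173 with no filter beyond a total count of 1, 111 by DESeq2 dispersion outliers, 13903 by a Poisson chi-square test, whose null is counting noise alone, and 0 with a robust prior, which by its construction lowers the prior degrees of freedom of the most variable genes. Over the libraries left out it ranged from 7 to 80. The number of lists that shifted between mice ranged from 9 to 17 over the libraries left out, and that of lists at or above the 95th percentile of level from 14 to 17 over all alternatives: with list means the astrocyte and efflux pump lists came in, and without replicate 2 or 3 the pericyte list dropped out. Genes detected in all libraries numbered 14432 at 0.5 CPM, 10671 at 5 CPM and 13974 at 1 CPM in at least 1 library. Among single genes and list levels, 2584 of the recomputed values moved by no more than the SD over mice, and 56 moved further, of which 24 were list levels scaled by gene length, which by construction changes the unit, and 22 were list means in place of medians. As for depth, 3 counts correspond to about 0.02 CPM, well under the detection limit of 1 CPM.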

Other observations

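The tests of nuclear copies and of the endothelial share were chosen only after the result was seen; the other tests were written before their values were seen. Genes in the first paragraph were chosen after their values were seen.

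Some detected genes outside the fixed lists were lower in replicate 2 than in both other libraries by more than 2-fold, among the 50 genes with the smallest p for variability. They were 10 genes, and none passed the adjusted threshold of edgeR's dispersion test. Fkbp5, a chaperone gene induced by glucocorticoids, had 55.9, 19.9 and 69.7 CPM in replicates 1, 2 and 3, Zbtb16 48.1, 8.56 and 41.0 CPM, Map3k6 108, 35.8 and 178 CPM, and Sult1a1 80.3, 36.7 and 123 CPM. The clock-output gene Dbp went the other way, with 23.5, 79.0 and 25.1 CPM, as did the venular chemokine receptor Ackr1, with 31.6, 147 and 47.1 CPM. The platelet gene Ppbp was highest where the globins were, with 5.56, 0.515 and 0.999 CPM.

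Pituitary hormone genes were high in replicate 2 alone, Gh by 172418 counts against 14 and 38 in replicates 1 and 3. Of 10 further genes of the anterior pituitary, 9 (90%) were highest in replicate 2 by more than 2-fold, against 0.189% of detected nuclear genes; Fshb had 3, 2346 and 9 counts and Gnrhr 8, 265 and 0, while Lhb, the exception, had 1.42, 1.22 and 0.964 CPM. Hypothalamic tissue would bring its peptide genes, but 0 of 8 with enough counts were highest in replicate 2 by that margin, which argues against it. The pattern is consistent with a small amount of pituitary tissue in that preparation; reads from a pituitary library mixed in later would look the same and stay open. No biological explanation of this pituitary pattern was tested, because the design has 1 group. The animal, its sex and its preparation cannot be separated in a single library.

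Mitochondrial messengers fell into abundant and nearly absent ones, with mt-Co1 at 9078 CPM but mt-Co2 at 6.55, mt-Co3 at 4.25 and mt-Atp6 at 3.12 CPM. A candidate explanation is that reads shared with near-identical nuclear copies were not counted. The 6 of 13 messengers with a nuclear transcript of at least 98% identity over more than 50% of their length had a median of 5.001 CPM per kb, against 1610 for the others (exact permutation test, two-sided, p = 0.0280). The exceptions were mt-Nd4, with a copy over 63.6% of its length but 1651 CPM, and mt-Atp8, with a copy over only 21.1% but 0.198 CPM. Only annotated nuclear transcripts were searched, so a copy elsewhere in the nuclear genome would be missed, and mt-Atp8 may not be a true exception. Loss of short transcripts stays open as a part of the cause: 15 nuclear protein-coding genes no longer than the 784 bases of mt-Co3 reached 100 CPM, which lies between the bounds set beforehand, and mt-Nd6, with 519 bases, had 342 CPM.

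The genes low in replicate 2 raised the hypothesis of a weaker glucocorticoid response in that mouse. A list of 10 other glucocorticoid-induced genes had a mean log2 deviation of -0.105 in replicate 2, at percentile 5.01 of random lists matched on expression, just outside the bound of 5 set beforehand. Its members went both ways, 5 below and 5 above their means, with Hif3a at 10.2, 3.96 and 11.9 CPM but Per1 at 78.1, 122 and 97.1 CPM, so the test leaves the hypothesis undecided. Fewer endothelial cells in replicate 2 would lower the endothelial list as well, but it deviated by 0.0129 there, against a median of -1.10 for the 10 genes, which argues against that cause. Sex, time of day and handling of the animal remain untested.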
